A study of Homo sapiens with 8 samples.

How the data were processed

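The series holds 8 chromatin immunoprecipitation sequencing (ChIP-seq) libraries of U2OS cells, a human osteosarcoma line. ChIP-seq sequences the DNA that an antibody pulls down from sheared chromatin, and a peak is a stretch where these reads exceed the background. Per the labels, 3 libraries belong to the NAT10 experiment (an input, an untreated and a β-hydroxybutyrate treated immunoprecipitation) and 5 to the CTCF experiment (an input, and immunoprecipitations with control or NAT10 siRNA, each untreated or treated with β-hydroxybutyrate). NAT10 is an RNA and protein acetyltransferase, CTCF is a DNA-binding protein that shapes chromatin loops, and β-hydroxybutyrate is a ketone body. Every group had 1 library, so no group has a replicate. Groups were taken from the sample titles.

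The processed data used here are 1 annotated peak list. Neither its header nor its peak names spell out a sample title, and the peak names begin with an abbreviation that the labels do not explain. The list was assigned to no library, so whether its peaks are of NAT10 or of CTCF is left open. Of the planned comparisons, 5 need peak sets of several libraries: NAT10 with and without β-hydroxybutyrate, CTCF with and without β-hydroxybutyrate, CTCF with and without NAT10 knockdown in treated and in untreated cells, and the overlap of NAT10 and CTCF peaks. They were not analysed here. Distances to transcription start sites are not given in the list and were not analysed either. The design had set promoters by distance to the start site; the authors' own promoter class was used in its place.

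Per the submitters' processing notes, Bowtie2 2.1.0, MACS2 2.1.1 and the hg19 build were used; the settings are not given in the sources used here. Per the file headers, the deposited columns hold each peak's coordinates, width, summit, pileup signal and fold enrichment ratio. The headers of 2 deposited columns had been overwritten by a spreadsheet error. From their place in the MACS2 layout and their values they are the −log10 p-value and the −log10 q-value of each summit, as the authors' peak caller gave them. All these scores are the authors' own. In the authors' deposited table the smallest −log10 p-value is 2.30, so every summit had a p of 0.00499 or less, and the peak numbers run without gaps to 34647. The authors also added a feature class, an Ensembl gene identifier, a gene symbol and Gene Ontology terms, from an annotation not given in the sources used here. The promoter intervals in it were at least 2001 bp long.

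The local background of each summit was recovered from the deposited values, as (pileup + 1) / fold enrichment − 1, with the MACS pseudocount of 1. A Poisson model with this background returned the deposited p of 100% of the summits within 0.005 on the log10 scale. The background values had a floor at 1.52 reads, shared by 42.5% of summits. Above the floor, 98.1% of the distinct values were whole numbers of reads, within 1e-04, in windows of the fragment length, 1 kb or 10 kb. The best match over fragment lengths from 150 to 300 bp was 224 bp, which is also the shortest peak, with each background read counted as 0.685. MACS2 counts background reads in such windows when it is given a control library. The library totals are not in the list. In MACS2 the floor is the genome average of the immunoprecipitated reads, so the floor and the fragment length give 6.81 immunoprecipitated reads per kb and 9.93 control reads per kb of the effective genome, a control deeper by a factor of 1.46. At this depth summits at the floor were listed from a pileup of 5 reads.

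Summits were merged to peaks by their shared coordinates, with the summit of highest fold enrichment and the lowest q standing for the peak. Shares have exact Clopper-Pearson 95% intervals and densities exact Poisson 95% intervals. Both cover counting error only and say nothing about the spread between cultures. Peaks per Mb use the distance from the first to the last peak of each chromosome. Gene symbols were matched to symbols or unique synonyms of the NCBI RefSeq gene table for GRCh38.p14, used for names and gene types only: 7301 of 8237 symbols matched, and 16 symbols had been turned into dates by a spreadsheet. The file names at most 1 gene per peak, so overlapping genes cannot be told apart. Of 20415 peaks with a feature class, 3202 carry no gene name, and 1183 of 1584 promoter-class peaks carry one. Peaks without a gene name do not enter the gene counts and list tests.

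Before the data were examined, 17 gene lists with 582 entries were fixed, of which 576 matched: chromatin architecture, replication, histones, nucleolus, ribosomal proteins, ketone metabolism, acylation enzymes, cell cycle, HOX genes, protocadherins, imprinted genes, bone and mesenchymal genes, and hepatocyte, neuron, blood, epithelial and olfactory genes. Each was compared with the other protein-coding genes among 20056 by a two-sided Fisher's exact test of genes with a promoter-class peak, with Benjamini-Hochberg adjustment over the lists. The strength of a list with at least 3 such genes was set against 10000 random gene sets of the same size. Genes are not replicates, so these tests describe this list. Genes are named by a rule fixed in advance: the 10 protein-coding genes with the highest fold enrichment at a promoter-class peak with ties, the 2 strongest of each list, and NAT10, CTCF, MYC, RUNX2, H19 and IGF2. A gene that the rule takes in is not reported here. Genes outside the rule are said to have been chosen after their values were seen.

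On simulated data with the 20056 genes, a list of 53 genes whose share with a promoter peak was multiplied by 5 was called in 86 of 100 simulations, and 1 of 1700 tests of unchanged lists was called. Most lists are shorter. Neither shorter lists nor a lowered share were simulated, so this rate does not carry over to them. The recovery of the background was also tested on simulated data. Some alternatives were added after seeing the data. Alternatives were stricter q and fold thresholds, removal of the widest 5% of peaks or of peaks at 10 times the floor or more, counts per summit, other annotation classes and another gene background. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.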

Results

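The peak list covered 34647 peaks with 34690 summits in U2OS cells on hg19. The median peak was 289 bp wide (quartiles 250 and 358 bp), and the median pileup at a summit was 7 reads (quartiles 6 and 8). The series measured NAT10 binding with and without β-hydroxybutyrate, and CTCF binding with and without β-hydroxybutyrate and NAT10 knockdown, with 1 library in each of 8 groups. The list is not tied to one of these libraries, and whether its peaks are of NAT10 or of CTCF is left open, so the results below describe where its peaks lay and how strong they were, and make no comparison between treatments. The depth recovered from the list was 6.81 immunoprecipitated and 9.93 control reads per kb of the effective genome.

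The strongest enrichment lay at the start of EEF1A1, which encodes the translation elongation factor that brings aminoacyl-tRNA to the ribosome. Its peak, in the 5′ UTR class on chromosome 6 from 74229953 to 74230933, held 3 summits and reached a pileup of 35 reads, a fold enrichment of 7.04 and a q of 1.74e-15. The next peak by fold enrichment, 6.33, had no annotated feature and lay on chromosome 1 from 181104119 to 181104456, with a q of 1.84e-10. An intron of TMEM132B followed at a fold enrichment of 5.58 and a q of 0.000311. These 3 peaks were chosen after their values were seen. EEF1A1 has processed pseudogenes elsewhere in the genome, so its value is uncertain.

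Most peaks were much weaker. The median fold enrichment was 2.76 (quartiles 2.38 and 3.06), and 8 peaks reached 5 or more. The median q was 0.734, and 119 peaks (0.343%) had a q under 0.05. The peaks with the lowest q were not those with the highest fold. A peak of 1940 bp on chromosome 21 from 9825555 to 9827494 had the lowest q, 9.21e-35, at a summit with a fold enrichment of 1.59 and a pileup of 1006 reads. The recovered background of that summit was 634 reads, 416 times the genome floor. Of the 11 peaks with a q under 1e-05, 9 had a background at least 10 times the floor; the other two were EEF1A1 and the unannotated peak on chromosome 1 at 181104119. An intron of HFM1, a meiotic helicase gene, carried 1 of the 9, with 243 reads over a background of 115, and an intron of the myosin gene MYO1D another, with 84 reads over 25.4. Both genes were named after their values were seen.

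Which parts of genes the peaks occupied was described with the deposited feature classes. Introns held 16145 peaks (46.6%, 95% interval 46.1 to 47.1%), and 14232 (41.1%, 40.6 to 41.6%) lay in no annotated feature. Exons held 6.46% (6.21 to 6.73%), promoters 4.57% (4.35 to 4.80%), 5′ UTRs 1.20% (1.09 to 1.32%) and 3′ UTRs 0.0895% (0.0608 to 0.127%). Median fold enrichment differed little between classes, from 2.50 in 3′ UTRs to 2.76 in 5′ UTRs, exons and the unannotated class. No genome share of these classes was computed, so the shares are not compared with chance.

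The 5′ UTR class was more frequent among the peaks with a q under 0.05, a threshold chosen after seeing the data. It held 6 of 119 peaks with a q under 0.05 (5.04%, 1.87 to 10.7%) and 410 of 34528 others (1.19%), an odds ratio of 4.42 (two-sided Fisher's exact test, p = 0.00321, adjusted p = 0.0193 over 6 classes). Besides EEF1A1, the 6 were at CADPS2, a regulator of dense-core vesicle release (fold enrichment 4.98), and CACNG2, an AMPA receptor subunit partner (4.91). The others were at KPNA2, a nuclear import adaptor (4.82), CECR2, a bromodomain protein of chromatin remodelling complexes (4.75), and RPS27L, a ribosomal protein paralog (4.01). The 6 genes were named after their values were seen. Introns held 36.1% of the peaks with a q under 0.05 and 46.6% of the others, which did not pass the adjusted threshold (exact test, adjusted p = 0.0803), and promoters held 7.56% against 4.56% (adjusted p = 0.181). With a q under 0.1 in place of 0.05, the 5′ UTR odds ratio was 2.02 and the test no longer passed (Fisher's exact test, p = 0.0508). Fold enrichment did not show this excess: 5′ UTRs held 1.225% of peaks at or above the median fold and 1.201% of all peaks.

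**Figure D1:**
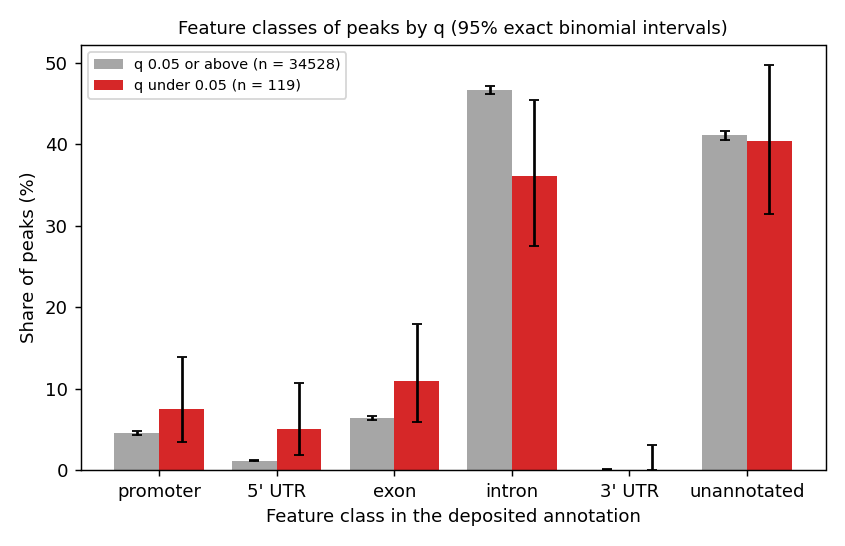
Share of peaks (%) in each deposited feature class for the 119 peaks with a q under 0.05 and the 34528 others, with bars from 0 and exact 95% binomial intervals. The 5′ UTR class takes 5.04% of the peaks with a q under 0.05 and 1.19% of the others.

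Promoter-class peaks were found at 847 protein-coding genes, 4.22% of those in the reference. Of all 1584 promoter-class peaks, 9 had a q under 0.05, so these genes and the list tests below rest mostly on peaks with a higher q. The promoter peak of highest fold at a protein-coding gene was at GAS6, a ligand of the TAM receptor kinases. It lay on chromosome 13 from 114540284 to 114540602, with a fold enrichment of 4.98 and a q of 0.00493. PRSS21, a serine protease gene, followed at a fold enrichment of 4.68 and a q of 0.0207. BRD3, which encodes a BET bromodomain reader of acetylated histones, had a promoter peak on chromosome 9 from 136918850 to 136919560 at 4.28 and a q of 0.0158. GGA1, a Golgi sorting adaptor gene, stood at 4.24 with a q of 0.0391, and AQP2, the vasopressin-regulated water channel gene, at 4.01 with a q of 0.0314. CYP4F2, a fatty acid hydroxylase gene (4.36), COL16A1, a collagen gene (4.21), and MGAT5B, a glycosyltransferase gene (4.09), missed a q of 0.05. Genes tied for the remaining places, at a fold enrichment of 3.96 and a q of 0.192, included LAYN, LSP1, MYOM2 and PGA5. PGA5 is a pepsinogen gene with near-identical neighbouring copies, so its peak is uncertain.

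The gene lists tested whether genes of replication, chromatin architecture, ketone metabolism and other groups carried promoter peaks more often than other genes. By two-sided Fisher's exact test, 0 of 17 lists passed an adjusted p of 0.05 and 0 passed an unadjusted one, with a smallest adjusted p of 0.541. Among the replication genes, 4 of 53 (7.55%) had a promoter peak, against 4.21% of other genes (exact test, adjusted p = 0.640). They included TIMELESS, a replication fork protection gene (fold enrichment 3.56), and MCM4, a subunit of the replicative helicase (2.77). Of the chromatin architecture list, 1 of 28 had one, the condensin gene NCAPG2 at 2.41. Of the ketone body list, 2 of 26 did: PPARA, a nuclear receptor of fatty acid metabolism (3.27), and CPT1A, the mitochondrial carnitine palmitoyltransferase (2.38). The acylation list had 1 of 29, BRD3.

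Among nucleolar genes, 2 of 45 had a promoter peak, UTP18 at a fold enrichment of 3.27 and WDR43 at 2.33, both genes of ribosomal RNA processing. Ribosomal protein genes had 4 of 77, led by RPS7 at 3.17 and RPLP1 at 3.12. Cell cycle genes had 3 of 42, led by the mitotic kinase gene PLK1 at 3.17 and the phosphatase gene CDC25B at 3.08. Imprinted genes had 3 of 22, led by PHLDA2 at 2.83 and MAGEL2 at 2.55 (exact test, adjusted p = 0.541). Bone and mesenchymal genes had 2 of 25, the collagen gene COL3A1 at 2.77 and the transcription factor gene PRRX1 at 2.41. HOX genes had 1 of 39, HOXD10 at 2.77. Neither the 53 protocadherins, the 35 replication-dependent histone genes, the 20 neuron genes nor the 20 olfactory receptor genes had any. Few were expected in lists of this size. The exact test did not set these lists apart (unadjusted p = 0.174 for the protocadherins and 0.403 for the histone genes).

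Among lists of other cell types, 3 of 20 blood genes had a promoter peak, led by HBB at 2.62 and CD79A at 2.41 (exact test, adjusted p = 0.541). The hepatocyte list had 2 of 21, TF at 3.01 and SERPINA1 at 2.38, and the epithelial list 1 of 17, CLDN3 at 2.41. HBB has close paralogs beside it, so its value is uncertain. At the promoter peaks of list genes given here by fold enrichment, q was 0.325 or above except at BRD3. Promoter peak strength did not set any list apart: for the 5 lists with at least 3 such genes, the median fold enrichment lay between percentiles 16.7 (blood) and 82.0 (cell cycle) of random gene sets.

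NAT10 and CTCF, the proteins immunoprecipitated in the series, each had 1 intron peak at their own genes, with fold enrichments of 2.52 and 2.42 and a q of 0.734. RUNX2, the master transcription factor of bone, had 4 intron peaks, the strongest at a fold enrichment of 3.81 and a q of 0.192. MYC had 1 exon peak on chromosome 8 from 128751069 to 128751337, with 15 reads over a background of 5.43, a fold enrichment of 2.49 and a q of 0.484. The numbers of peaks assigned to H19 and IGF2, the imprinted pair with a CTCF-bound control region, were 0 and 0. Only peaks that carry these gene names were counted, so peaks at the control region itself were not looked for.

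Peaks were spread unevenly over the chromosomes. Chromosome 19 had the highest density at 23.1 peaks per Mb (21.9 to 24.3), followed by chromosome 22 at 22.6 (21.0 to 24.2) and chromosome 17 at 19.3 (18.3 to 20.2). Chromosome 4 had the lowest density of the autosomes and X at 5.39 (5.06 to 5.73), below chromosome 18 at 6.64 (6.08 to 7.24) and X at 7.04 (6.62 to 7.47). Across these 23 chromosomes, density rose with the share of peaks whose background lay above the floor (Pearson r = 0.724, permutation p = 0.00013; Spearman rho = 0.75, permutation p = 0.00012). Without chromosomes 4 and 14, the farthest from the median share, r was 0.658 (permutation p = 0.00134). Peaks above the floor count in both measures, so part of a positive relation is built in, and permutation does not remove it. No other relation was computed across chromosomes.

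**Figure D2:**
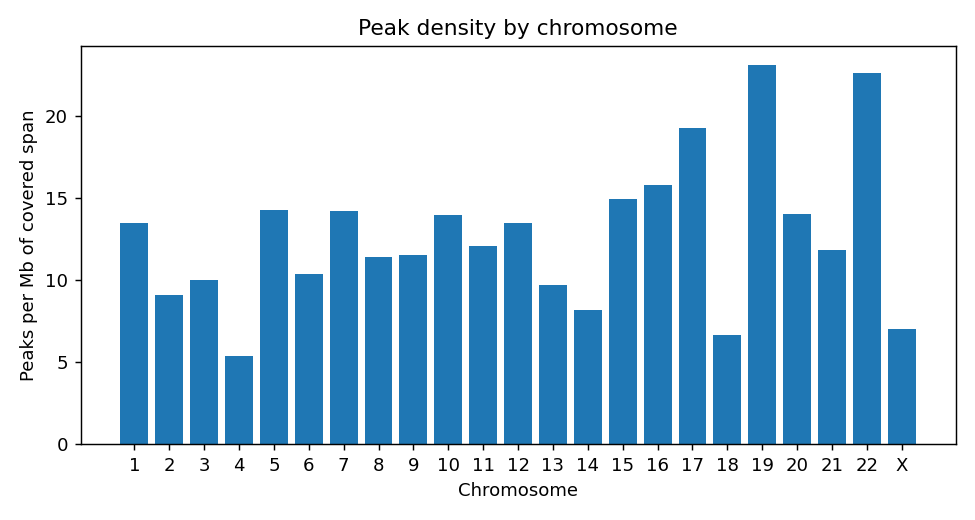
Peaks per Mb of the span between the first and last peak of each chromosome, as bars from 0 for the autosomes and X. Chromosomes 19 and 22 stand highest, at 23.1 and 22.6, and chromosome 4 lowest, at 5.39.

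The recovered background also changed in long blocks, whose bounds were chosen after the values were seen. On chromosome 1 the median background at peaks was 1.52 (quartiles 1.52 and 1.52) up to 30 Mb, 1.89 (1.53 and 2.19) from 30 to 60 Mb, 3.38 (2.74 and 3.98) from 65 to 120 Mb and 2.23 (1.95 and 2.56) beyond 150 Mb. Density on chromosome 1 was 17.1 peaks per Mb (15.7 to 18.7) and 18.7 (17.2 to 20.35) in the first pair of blocks, where 19.6% and 76.5% of peaks lay above the floor. It was 13.7 (12.8 to 14.7) and 13.6 (12.9 to 14.4) in the later ones, where 98.9% and 93.3% did. On chromosome 5 the median background was 3.43 (2.86 and 4.30) up to 45 Mb and 1.58 (1.52 and 1.92) beyond 50 Mb, with 18.7 peaks per Mb (17.5 to 20.02) in the first block and 13.0 (12.4 to 13.6) in the second. The first 5 Mb of chromosome 5 alone held 258 of the 842 peaks of the first block. On chromosome 8 the median background was at the floor up to 65 Mb and 2.76 (2.44 and 3.22) beyond 130 Mb, where density was 24.0 peaks per Mb (21.7 to 26.5) against 8.62 (7.92 to 9.36). The stretch from 140 to 145 Mb of chromosome 8 alone held 183 of the 388 peaks beyond 130 Mb. On chromosome 2, density fell from 11.4 peaks per Mb (10.8 to 12.0) before 130 Mb to 6.46 (6.0 to 6.95) after it, and the share of peaks above the floor from 51.4% to 14.4%. Chromosome 4 had 17.8 peaks per Mb (15.3 to 20.6) before 10 Mb and 4.69 (4.38 to 5.02) after it, with 29.2% and 10.4% of peaks above the floor.

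**Figure D3:**
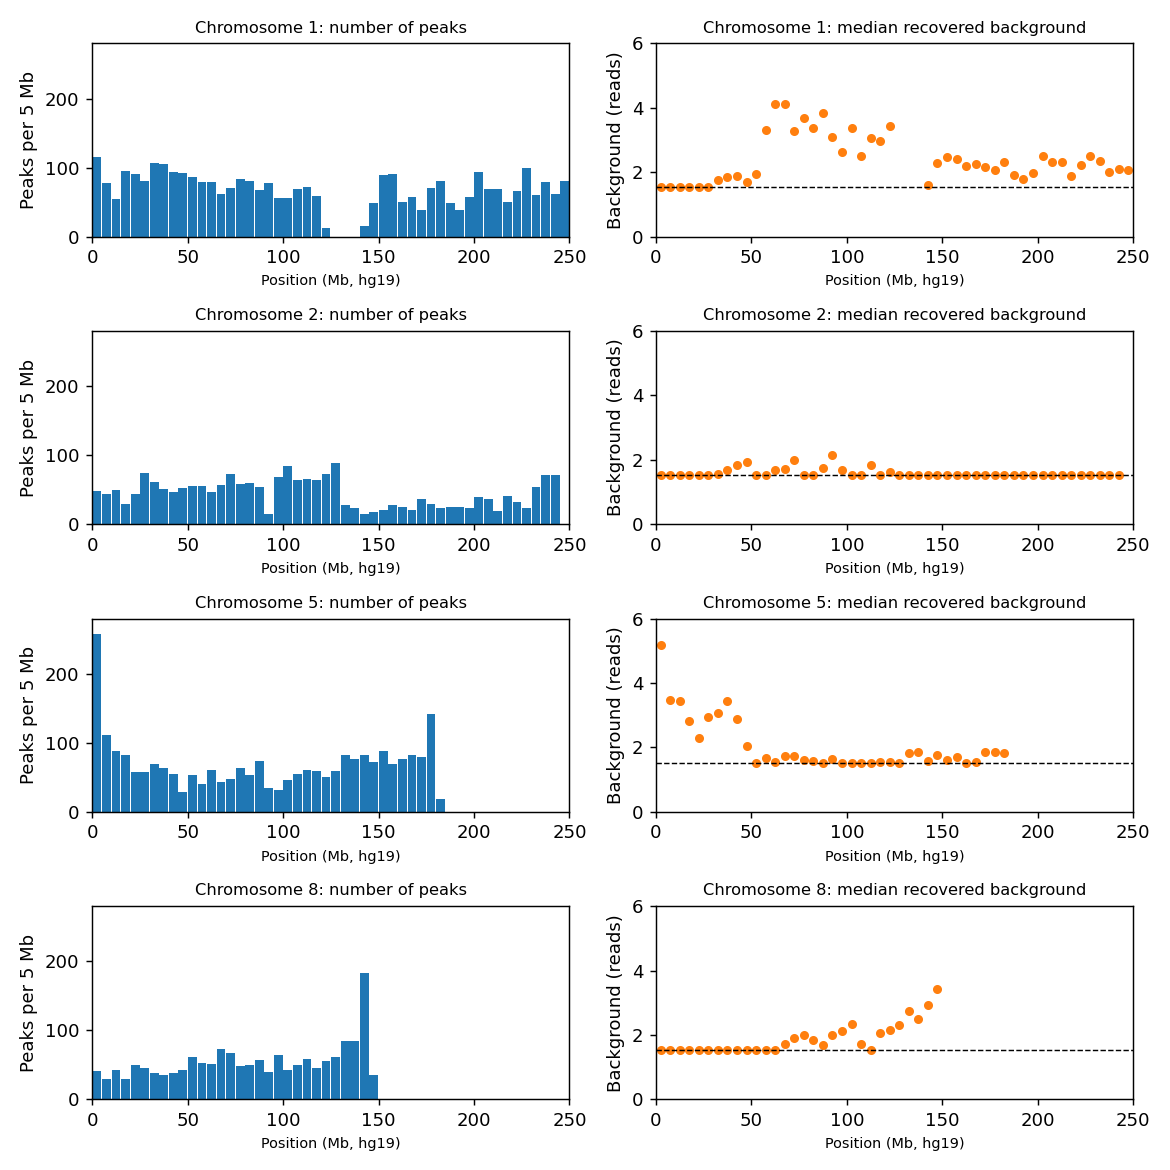
Number of peaks per 5 Mb (left, bars from 0) and median recovered background in reads (right, 5 Mb bins with at least 10 peaks) along chromosomes 1, 2, 5 and 8, with the floor of 1.52 dashed. The background is raised between 65 and 120 Mb of chromosome 1 and before 45 Mb of chromosome 5, and peak number drops after 130 Mb of chromosome 2.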

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

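The thresholds of a q under 0.05 and under 0.1, counts per summit, removal of peaks at 10 times the floor background or more, and the annotation classes beyond promoters were chosen after seeing the data. The list shrank from 34647 peaks to 11 at a q under 1e-05, to 8 at a fold enrichment of 5 or more and to 119 at a q under 0.05. It held 34644 on the autosomes and X, 34634 without high-background peaks and 34690 per summit. At a q under 1e-05, feature shares rested on 11 peaks: 18.2% promoter, 9.09% 5′ UTR, 18.2% exon, 27.3% intron, 0% 3′ UTR and 27.3% unannotated. At or above the median fold, without the widest peaks and per summit, each class share stayed within the interval of the full list. The excess of 5′ UTR peaks had an odds ratio of 5.70 per summit, where EEF1A1 counts once for each of its summits, and 4.90 without high-background peaks. At a q under 0.1 the odds ratio was 2.02 and missed the threshold (Fisher's exact test, p = 0.0508). The cause was not tested. Gene lists past the adjusted threshold of Fisher's exact test numbered 0 at or above the median fold (0 unadjusted), 0 against the genes the list names (2 unadjusted), 0 with 5′ UTRs added (2 unadjusted) and 5 with peaks of any annotated class. No list strength left the central range of random sets under its alternatives. Not run were wider and narrower promoters, classes by distance and distances to start sites, which need start sites, the overlap alternatives, which need other peak sets, and the gene lists at a q under 1e-05, where no promoter peak named a protein-coding gene. No paired analysis was possible because every group has 1 library and the list names none. At the recovered depth, summits at the floor were listed from 5 reads.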

Other observations

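The tests in this part were chosen after the result was seen, except those of floor-background peaks in the last 5 Mb of chromosomes and of background at gene starts. With peaks of any annotated class, 5 of 17 gene lists differed from other protein-coding genes (two-sided Fisher's exact test, Benjamini-Hochberg over the lists). A peak lay in 28 of 53 replication genes (52.8% against 34.8%, exact test, adjusted p = 0.0366). Among them were MCM4, MCM6 and MCM10, the origin recognition genes ORC2, ORC3 and ORC5, and the initiation factor gene TICRR, named after their values were seen. A peak also lay in 14 of 20 neuron genes (70.0%, exact test, adjusted p = 0.00928), such as the glutamate receptor gene GRIN2B. By the same exact test the shares were lower for ribosomal protein genes (11 of 77, 14.3%, adjusted p = 0.00054), HOX genes (6 of 39, 15.4%, adjusted p = 0.0366) and histone genes (1 of 35, 2.86%, adjusted p = 0.000139).

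A candidate explanation for this split is that long genes offer more intron sequence in which a weak peak can fall. In the neuron list, 14 of 20 genes had an intron peak, against 27.2% of other genes (Fisher's exact test, p = 8.07e-05), and 2 had a promoter, 5′ UTR or exon peak, against 12.6% of others (p = 1). The same 14 genes made this list pass with any annotated class, so its intron test largely repeats that result. With 20 genes the test of the other classes could show little. Intron peaks lay in 21 of 53 replication genes (Fisher's exact test, p = 0.0453), 4 of 39 HOX genes (p = 0.0178) and 6 of 77 ribosomal protein genes (p = 2.96e-05), and promoter, 5′ UTR or exon peaks in 9 (p = 0.302), 2 (p = 0.225) and 6 (p = 0.298) of them. The histone genes say nothing here, since they lack introns. Gene length itself was not tested, and no biological explanation was tested.

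The peaks with the lowest q may mark sequence that is present in many copies but collapsed in the reference, or strong local enrichment. Their q values do not decide between them. The median background of the 11 peaks with a q under 1e-05 was 31.5 times the floor, and their median fold enrichment was 2.20, against 4.57 for the other peaks with a q under 0.05. Selection by q fixes much of both values: a q under 1e-05 needs a fold enrichment of 6.73 at the floor but of 2.14 at 31.5 times the floor. EEF1A1 and the unannotated peak on chromosome 1 at 181104119 had fold enrichments of 7.04 and 6.33. At the other 9 of the 11 peaks the background was at least 10 times the floor. The background is counted in control reads, so this rise is not itself enrichment by the antibody. The cause of the excess over it was not tested. Copy number of these sequences was not measured here, and no biological explanation was tested.

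The uneven spread of peaks may partly follow the number of control reads in each region. Across 587 bins of 5 Mb with at least 10 peaks, peak number rose with the median recovered background (Spearman rho = 0.50, 1000 circular shifts, p = 0.001, the smallest they can give). Chromosome 1 did not follow it throughout: in blocks chosen after their values were seen, density was 17.1 peaks per Mb up to 30 Mb with 19.6% of peaks above the floor, 18.7 from 30 to 60 Mb with 76.5%, and 13.7 from 65 to 120 Mb with 98.9%. Whether the raised background on chromosomes 1, 5 and 8 reflects copy number in this aneuploid line was not tested, nor were mappability and base composition, and the background is known only at peaks. In the bins, peaks above the floor add to the number and can raise the median, so part of that relation may be built in. No biological explanation was tested.

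Density in the last 5 Mb of a chromosome was higher than in the rest on 21 of 23 chromosomes, with a median ratio of 2.13 (exact sign test, p = 6.60e-05). Only the end of highest coordinates was taken, and the first 5 Mb counted in the rest. Among peaks at the floor background, which are scarce where the background is raised, the median ratio was 1.55 and was above 1 on 15 of 23 (exact sign test, p = 0.21). Of the 2000 peaks in promoters and 5′ UTRs, 66.6% had a background above the floor, against 52.7% of unannotated peaks (Fisher's exact test, p = 5.23e-32). The share was 71.2% (66.5 to 75.5%) in 5′ UTRs alone, 65.3% (62.9 to 67.7%) in promoters, 69.1% (67.1 to 71.0%) in exons and 58.9% (58.1 to 59.6%) in introns. Background changed in long blocks, so neighbouring peaks are not independent, and the p of the exact test between classes is too small. Feature class was not separated from region. Of 802 Gene Ontology terms tested among the genes the list names, 0 were over- or under-represented among the 1188 genes with a promoter or 5′ UTR peak by Fisher's exact test with Benjamini-Hochberg adjustment (smallest adjusted p = 0.335), and 36 had an unadjusted p under 0.05.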
